A study of Brassica oleracea with 4 samples.

How the data were processed

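RNA was taken from hypocotyls of broccoli microgreens at 10 days. Per the labels' protocols, seedlings grew on hydroponic pads at 25 °C, in the dark for the first 4 days and then in 12 h light and 12 h dark at 42 µmol per second and square metre. They were sprayed daily with water or with calcium chloride at 1, 10 or 20 mmol/L, and RNA was sequenced from the water and 10 mmol/L seedlings. Total RNA was purified with a column kit, and libraries were made with the Illumina TruSeq RNA kit, per the labels' protocols. The labels give 2 libraries per spray, 4 in all, and do not say whether these came from separate trays.

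The deposited table holds 135 genes. Per the file headers, the authors gave each gene an RPKM for the control and an RPKM for calcium; the control column was taken as the water group, the only other group in the labels. How the authors combined the libraries of a group into 1 value is not given in the sources used here. The submitters' processing notes name CASAVA, without a version. The aligner, the genome build and the annotation are not given in the sources used here. The deposited log10 column of the control was checked to be the log10 of its RPKM column, and that of calcium was not checked. The deposited fold change was checked to be the ratio of the group RPKM values. The authors also deposited an adjusted p-value per gene, under a header that names a false discovery rate, without the test in the sources used here. A cluster number per gene is the authors' own. The table was checked to hold only genes with at least a 2-fold difference, and its highest deposited adjusted p-value is 0.0423. The lowest RPKM in the higher of a gene's groups is 25.8, and the smallest difference is 21.5 RPKM. RPKM depends on the annotated gene length and on the total of mapped reads. Neither is given, so reads could not be recovered and the depth of each library is unknown.

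The planned test, limma on log2(RPKM + 1) across 4 libraries, needs a value per library and was not run. For this case the plan, fixed before the data were examined, was to give both group values without a test. Fold differences in the text are ratios of the group RPKM values, and no p-value, standard deviation or count adjusted over a list alone was computed. Genes were named by a rule also fixed before the data were examined. It takes the 12 highest and the 12 lowest log2 ratios with a pseudocount of 1 RPKM, among genes with at least 5 RPKM in a group. It also takes up to 3 members with the largest absolute ratio from each gene list, and gives 44 genes. Other genes in the text were chosen after their values were seen, to fill in a list. The 20 gene lists, 3 of which mark other tissues, were word patterns fixed before the data were examined and matched to the deposited annotation. They took in 56 of the 135 genes, with 1 gene in more than 1 list. None of the 135 identifiers was found in the reference gene table at hand, so gene names come from the deposited annotation alone.

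For lists with at least 5 members, the median log2 ratio was placed among 10000 random lists of the same size from the 135 genes, matched in 5 bins of mean expression. The random lists did not keep together genes that match the same Arabidopsis gene. They could also draw the list's own members. Placing medians among random lists was not in the plan, and the 135 selected genes are not a background of all genes. The z of a test of 2 proportions was computed as the difference of the RPKM values, scaled by the ratio of totals, over its binomial error. The ratio was scanned in steps of 0.0005. Both computations were tested on simulated data. In a simulation of 10000 genes the ratio of totals was recovered within 0.0005. The simulated p-values came from the same z, so this tests the scan alone and not which test the authors used. In the 135 genes, 200 random lists of 12 had a mean percentile of 49.0, and lists of 12 drawn from the higher genes had a mean percentile of 97.7. Pseudocounts of 0, 0.1 and 5 RPKM, filters, quantile normalization, a median shift and stricter thresholds were tried as alternatives. The quantile normalization and the median shift were applied to the log2(RPKM + 1) values, so both also carry a pseudocount of 1 RPKM. Both used only the 135 selected genes, with no unchanged gene among them. They therefore do not normalize the libraries, and a smaller ratio under them does not show that a difference is weak. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.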

Results

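Transcript abundance was measured by RNA sequencing in hypocotyls, the embryonic stems, of broccoli (Brassica oleracea) microgreens harvested at 10 days. Seedlings had been sprayed once a day with 10 mmol/L calcium chloride or with water, and the labels give 2 libraries for each spray. The values used here form a table of 135 genes with 1 RPKM value (a read count scaled to the length of the gene and to the total of mapped reads) for each group. No value of a single library is among them, so the values below carry no replicate error and no test of the difference could be made. The number of reads behind each value is unknown, and no counting interval is given. Every gene in the table had at least a 2-fold difference, and the highest adjusted p-value in the authors' deposited table was 0.0423. The table is thus a selection of genes that differed, and genes outside it were not analysed here. Its broccoli identifiers are named through the Arabidopsis gene that each matches. That match was given for 108 genes and not for the remaining 27. Genomic positions are not given in the sources used here.

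The comparison asks which transcripts differ in the hypocotyl after a calcium spray, with an eye to the expansion of hypocotyl cells. Gene lists were matched on annotation words. The genes that were higher with calcium included all 14 listed for calcium signalling and transport, 8 of 9 for defence and 5 of 6 for cell wall loosening. Those that were lower included 12 genes of the photosynthetic apparatus and 6 genes annotated as trypsin or protease inhibitors, the last a group chosen after the values were seen. In all, 71 genes were higher with calcium and 64 were lower. The higher genes had a median difference of 2.98-fold and reached 26.6-fold, while the lower genes had a median of 3.11-fold and reached 86.4-fold. At least a 3-fold difference was found in 34 of the higher genes and in 34 of the lower genes. The authors' deposited table placed all 71 higher genes in its cluster 1, and divided the lower genes into cluster 3, with 56 genes up to 6.45-fold lower, and cluster 2, with 8 genes from 8.13-fold lower upwards.

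**Figure D1:**
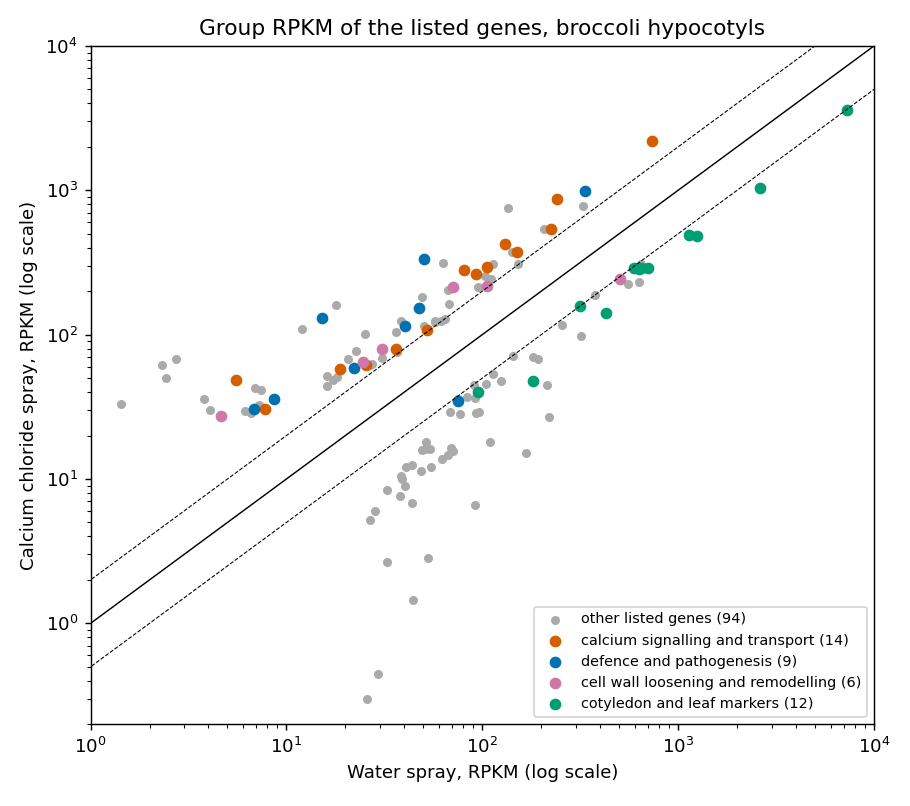
RPKM of each of the 135 listed genes with water spray (horizontal axis, log scale) and with calcium chloride spray (vertical axis, log scale), 1 point per gene and 1 value per group without replicate error. The solid line marks equal values and the dashed lines a 2-fold difference. The 14 calcium genes lie above the lines and the 12 cotyledon and leaf markers below them.

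The 12 genes highest on the log2(RPKM + 1) scale had plain RPKM ratios from 5.57-fold to 26.6-fold. On the plain ratio 3 genes outside these 12, Bo6g094710 at 6.16-fold, Bo3g175620 at 5.91-fold and Bo01260s010 at 5.58-fold, stood above the lowest of them. The largest ratio of RPKM was that of Bo9g167830, annotated as an auxin-responsive GH3 family protein, at 2.30 RPKM with water and 61.4 RPKM with calcium (26.6-fold). GH3 proteins join amino acids to acidic hormones, and the Arabidopsis gene it matches, AT5G13320, is known for a role in salicylic acid synthesis. ICS1 (Bo6g086860), isochorismate synthase of the salicylic acid pathway, was at 17.9 and 161 RPKM (8.97-fold higher). A homologue of plant defensin 1.3 (Bo6g086120) was 8.58-fold higher, and a putative chitinase (Bo4g020920), an enzyme that cleaves fungal cell walls, was 6.59-fold higher at 333 RPKM with calcium. A 2-oxoglutarate and Fe(II)-dependent oxygenase (Bo5g004490) was 23.1-fold higher, from 1.44 to 33.2 RPKM. The late embryogenesis abundant protein M17 (Bo4g190800) was 20.7-fold higher, from 2.42 to 50.1 RPKM. Plant cadmium resistance 2 (Bo8g106400) was 9.48-fold higher, and the calcium-binding EF-hand gene Bo6g062100 was 8.78-fold higher. The lipid transfer protein LTP3 (Bo2g026830) was 5.57-fold higher at 753 RPKM. The other 3 of these 12 genes had no annotation, among them Bo9g032500, which was 24.8-fold higher, and Bo33549s010, which was 9.08-fold higher. Ratios over a low value with water depend on what is added to both values. With 5 RPKM added, the log2 ratio went from 4.74 to 3.18 for Bo9g167830, from 4.63 to 3.23 for Bo9g032500, from 4.53 to 2.57 for Bo5g004490, from 4.37 to 2.89 for M17, from 3.24 to 2.22 for Bo8g106400 and from 3.13 to 2.35 for Bo6g062100.

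The 12 lowest genes on the log2(RPKM + 1) scale included 3 genes annotated to the Kunitz family of trypsin and protease inhibitors. On the plain ratio 1 gene outside these 12, without annotation, was 5.11-fold lower and so past the last of them. Bo00722s110 and Bo00722s060, which match the same Arabidopsis Kunitz gene, were 30.6-fold lower (44.2 against 1.45 RPKM) and 11.0-fold lower (167 against 15.2 RPKM). A further one, Bo6g116730, was 6.07-fold lower. The homologue of the DNA repair gene BRCA1 (Bo3g162790) was at 25.8 RPKM with water and 0.298 RPKM with calcium, or 86.4-fold lower. A gene of the CAP superfamily (Bo1g007900) was 13.9-fold lower, a peroxidase (Bo2g166040) 12.4-fold lower, and a GDSL-like lipase (Bo6g032890) 8.13-fold lower from 219 RPKM. The tonoplast intrinsic protein 2;3 gene (Bo7g077600), a channel of the vacuolar membrane, was 6.45-fold lower. The beta glucosidase gene BGLU18 (Bo6g028090), whose Arabidopsis counterpart releases abscisic acid from its glucose ester, was 4.98-fold lower, and a knottin family gene (Bo4g020910) was 4.76-fold lower. The 2 members without annotation, Bo2g017650 and Bo4g194410, were 66.2-fold and 18.7-fold lower. The size and rank of these ratios over values near 0 depend on what is added. With 1 and 5 RPKM added, the log2 ratio went from -6.43 to -4.37 and -2.54 for Bo3g162790, from -6.05 to -4.40 and -2.66 for Bo2g017650, and from -4.93 to -4.21 and -2.93 for Bo00722s110. With 5 RPKM added it was -2.30 for the peroxidase, -2.89 for Bo4g194410, -3.06 for Bo1g007900 and -2.05 for Bo7g077600, against -3.63, -4.22, -3.79 and -2.69 with none.

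All 14 genes of the list for calcium signalling and transport that stood in the table were higher with calcium, from 2.07-fold to 8.78-fold. In the same samples the cotyledon and leaf markers of the table were lower with calcium, by a median of 2.35-fold. Both homologues of CAX1, a vacuolar exchanger of calcium for protons, were higher: Bo4g187430 was at 242 and 874 RPKM (3.62-fold) and Bo4g029730 was 3.26-fold higher. The calcium pump genes ACA10, ACA1 and ACA11 were 2.76-fold, 2.20-fold and 2.07-fold higher. ACA11 (Bo6g072820) was under 2-fold with 5 RPKM added (1.97-fold). It was also under 2-fold when the log2(RPKM + 1) values of the 135 selected genes alone were quantile normalized (1.78-fold). The calmodulin-like gene CML41 (Bo7g100490) was 3.48-fold higher. The most abundant member, the EF-hand gene Bo4g197210, was at 737 RPKM with water and 2201 RPKM with calcium. BON3 (Bo8g112290), a copine that binds phospholipids in the presence of calcium, was 3.94-fold higher. The median log2 ratio of the list, 1.52 on the log2(RPKM + 1) scale, lay at percentile 99.1 among 10000 random lists of equal size drawn from the table and matched on mean expression. In these, 95% of the medians lay between -1.28 and 1.45. This percentile was not planned, describes the 2 group values and is not a test across libraries. Lists of 12 drawn from the higher genes had a mean percentile of 97.7, so it largely restates that all 14 were higher. The list also holds 2 genes each for AT2G38170 (CAX1), AT2G46600, AT2G41410 and AT5G39670. Genes that shared a match always lay on the same side, and random lists did not keep them together. The percentile may thus overstate how unusual the list is.

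**Figure D2:**
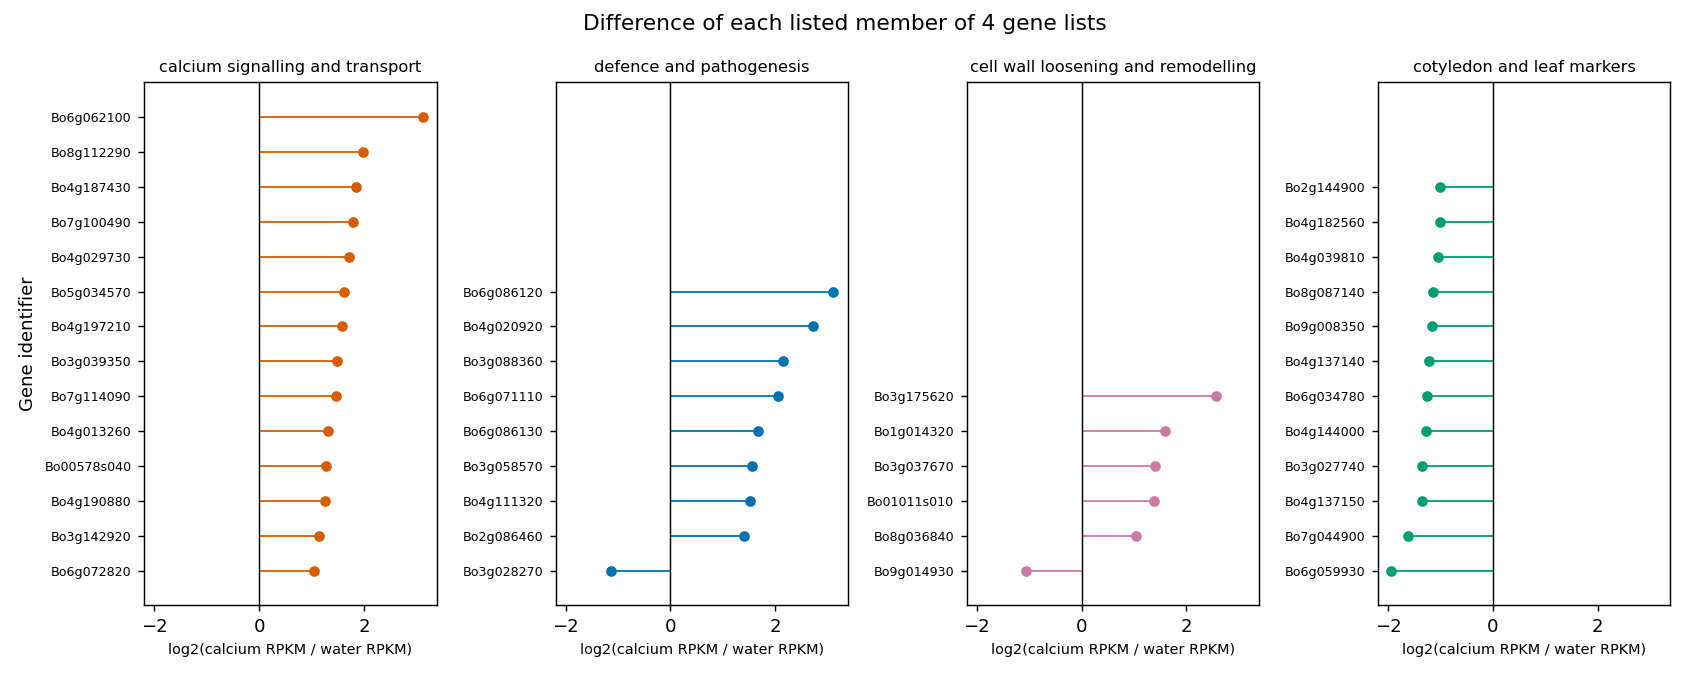
Log2 ratio of calcium RPKM to water RPKM (horizontal axis) for each listed member of 4 gene lists, 1 point per gene identifier (vertical axis), with no replicate error. All 14 calcium genes lie to the right of 0, all 12 cotyledon and leaf markers to the left, and 1 member each of the defence and cell wall lists lies to the left.

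For cell wall loosening and remodelling, the group closest to the question of cell expansion, 5 listed genes were higher with calcium and 1 was lower. Xyloglucan endotransglucosylase/hydrolases cut and rejoin the xyloglucan chains between cellulose fibres. The homologue of number 17 of that family (Bo3g175620) was at 4.61 and 27.3 RPKM (5.91-fold higher), the homologue of number 18 (Bo1g014320) was at 70.9 and 212 RPKM (2.99-fold higher), and XTH15 (Bo8g036840) was 2.06-fold higher. Under quantile normalization across the 135 selected genes alone, the log2 ratio of XTH15 was 0.53, below the 2-fold limit. With 5 RPKM added, that of Bo3g175620 went from 2.56 to 1.75. EXPA10 (Bo01011s010), an expansin, one of the proteins that loosen the wall during growth, was 2.59-fold higher, at 30.9 and 80.0 RPKM. The remaining members carry the annotation of the plant invertase and pectin methylesterase inhibitor superfamily and went apart. Bo3g037670 was 2.63-fold higher and Bo9g014930 was 2.09-fold lower, from 505 to 242 RPKM. They match different Arabidopsis genes, AT2G45220 and AT5G62360. The superfamily annotation does not show whether each encodes an enzyme or an inhibitor, so they need not be alike in function. The median log2 ratio of the list was 1.35, at percentile 80.4 of the matched random lists, beside a median log2 ratio of -1.22 for the cotyledon and leaf markers. The single match to the list for wall structure was M17, named above, which is annotated as both glycine-rich and late embryogenesis abundant.

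Of the 9 listed genes for defence and pathogenesis, 8 were higher with calcium and 1 was lower, in samples whose cotyledon and leaf markers were lower by a median of 2.35-fold. PR1 (Bo3g088360), a marker of the salicylic acid response, was at 6.85 and 30.5 RPKM (4.45-fold higher). The beta-1,3-glucanase PR-2 (Bo4g111320) was 2.87-fold higher, and PR-4 (Bo3g058570) was 2.96-fold higher and the most abundant of the list at 987 RPKM with calcium. The homologue of the transcription factor WRKY 70 (Bo6g071110) was 4.15-fold higher. Besides the defensin 1.3 homologue, the homologues of plant defensin 1.2C (Bo6g086130) and PDF1.1 (Bo2g086460) were 3.20-fold and 2.65-fold higher. A chitinase family gene (Bo3g028270) was 2.19-fold lower. The list holds only genes whose annotation matched its words. Outside it, the CAP superfamily gene Bo1g007900 was 13.9-fold lower and the glycosyl hydrolase gene Bo1g054940 was 4.59-fold lower. Both legume lectin genes and all 6 genes annotated as trypsin or protease inhibitors were also lower. Others outside it, such as both ICS1 genes and DMR6, were higher. Whether these genes act in defence was not examined, so the count of 8 of 9 depends on the words matched. The median log2 ratio of the list was 1.66, at percentile 97.6 of the matched random lists. The senescence list had 1 member, SAG13 (Bo9g166530), which was at 49.5 and 182 RPKM (3.68-fold higher).

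All 12 listed genes of the cotyledon and leaf marker list were lower with calcium, from 2.01-fold to 3.83-fold. They encode the chlorophyll-binding antenna proteins of the photosystems, the small subunit of the carbon-fixing enzyme RuBisCO, and a subunit of photosystem I. The most abundant gene in the table, Bo4g182560, annotated as LHCB1.3, was at 7288 RPKM with water and 3605 RPKM with calcium (2.02-fold lower). Quantile normalization gives the most abundant gene of both columns an equal value by construction, and so a log2 ratio of 0 for this gene. A further gene of that annotation (Bo7g044900) was 3.06-fold lower, and the LHCB1.4 homologue Bo3g027740 was 2.55-fold lower, from 2625 to 1031 RPKM. Of the 4 RuBisCO small subunit genes, Bo6g059930 was 3.83-fold lower (181 against 47.4 RPKM) and Bo4g137150 was 2.56-fold lower (1244 against 485 RPKM). PSAG was 2.38-fold lower and LHCA1 2.20-fold lower. The summed RPKM of the 12 genes was 15889 with water and 7147 with calcium. The median log2 ratio of the list, -1.22, lay at percentile 0.65 of the matched random lists. In a table with no gene under a 2-fold difference, this percentile largely restates that all 12 were lower. The list holds 2 genes for AT2G34430, 2 for AT3G27690 and 3 for AT5G38420. Random lists did not keep such genes together, so the percentile may overstate how unusual the median is. They could also draw the 12 genes themselves, which may have the opposite effect. The 12 genes also mark green leaf tissue, and the list had been set up to show cotyledon tissue in a hypocotyl sample.

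The other lists had 3 members or fewer in the table. Both listed members of the abscisic acid and jasmonate list were lower with calcium, but neither is annotated with abscisic acid. They were VSP2 (Bo2g159220), a jasmonate-responsive storage protein gene at 4.55-fold lower, and OPR1 (Bo2g091100), a 12-oxophytodienoate reductase gene at 2.73-fold lower. CYP79B2 (Bo7g118840), which makes a precursor of indole glucosinolates, was 3.88-fold lower. In the oxidative stress list the glutathione S-transferase GSTF2 (Bo3g052490) was 2.26-fold higher, with a log2 ratio of 0.68 under quantile normalization, while GSTF9 was 2.47-fold lower and the peroxidase named above was also lower. The 3 genes matched by the words of the nutrient and ion transport list were lower, but none of them is annotated as a transporter. They thus say nothing about transport, and the CAX1 and ACA genes of the calcium list were higher. The metallothionein MT3 (Bo3g066750), from a family that binds metal ions, was at 144 RPKM with water and 71.6 RPKM with calcium, and was 1.99-fold lower with 1 RPKM added. The others, Bo7g084180 and Bo2g140330 at 4.54-fold and 4.51-fold lower, match TSO2, the small subunit of ribonucleotide reductase, which supplies DNA precursors. Of the seed and embryo markers, M17 and a lipid transfer protein of the 2S albumin superfamily (Bo9g120390, 2.65-fold) were higher. The single root marker, the growth factor gene RGF9 (Bo2g166400), was 3.36-fold lower. No gene of the table matched the lists for lignin and phenylpropanoids, gibberellin and brassinosteroid, ethylene, ribosome and translation, cell cycle and chromatin, or reference genes. This does not show that such genes kept their level, since the table holds only genes that differed.

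In 13 cases, covering 27 genes, more than 1 listed gene matched the same Arabidopsis gene. The genes of each case lay on the same side, against a mean of 6.21 of the 13 cases when directions were shuffled 10000 times. The list percentiles treat such genes as independent. In 5 of the 13 cases the differences of the copies were more than 1.5 times apart, as for ICS1, where Bo6g086860 was 8.97-fold and Bo2g082320 was 3.23-fold higher. Whether reads were shared between such copies was not tested, and their single values are uncertain to that extent.

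The adjusted p-values of the authors' deposited table were ordered almost entirely by the 2 group RPKM values. A test of 2 proportions was recomputed from the RPKM values of each gene, and its z was set against the deposited adjusted p of the 94 genes for which that value was above 0. With a ratio of calcium to water totals of 0.979, the one that left the fewest pairs out of order, 1 of 4368 gene pairs was ordered differently. With equal totals, 159 pairs were. In the authors' deposited table the adjusted p was 0 for the other 41 genes, all of which had a z of at least 8.48.

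**Figure D3:**
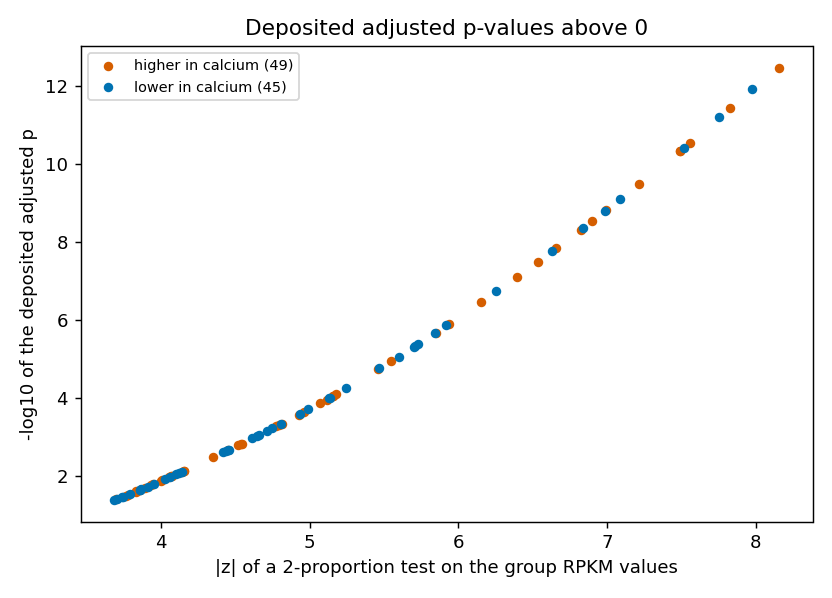
Absolute z of a test of 2 proportions on the group RPKM values (horizontal axis) against -log10 of the adjusted p in the authors' deposited table (vertical axis), 1 point per gene for the 94 genes with an adjusted p above 0, coloured by direction. The points form 1 rising curve, with 1 of 4368 pairs out of order.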

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

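The 3-fold limit, the adjusted p limit of 0.001, the count without leaf markers, the count with a pseudocount of 1 and the pseudocount of 0 were chosen after seeing the data. Raising the 2-fold limit to 3-fold left 68 of the 135 genes, 34 higher and 34 lower. Under each of the other settings the counts stayed within 1.5 times of the deposited 135, 71 and 64. They were lowest at a deposited adjusted p under 0.001, with 93 genes (49 higher, 44 lower). No filter on low values removed a gene. Every gene already met the 2-fold limit and the adjusted p limit of 0.05, and none from outside could enter. The counts could therefore only fall or stay, and neither they nor the filters show stability. Pseudocounts cannot turn the sign of a ratio, and the shift was too small to do so, which leaves quantile normalization as the setting that could. It equalizes the 2 columns of the 135 selected genes and does not normalize the libraries. Under it the medians of the 4 lists fixed before the data were examined that had at least 5 members were 1.29 for calcium signalling, 1.70 for defence, 1.24 for cell wall loosening and -1.21 for the leaf markers. Over all settings the median log2 ratio ranged from 1.29 to 1.53 for calcium signalling, from 1.58 to 1.70 for defence, from 1.24 to 1.38 for cell wall loosening and from -1.26 to -1.18 for the leaf markers. Of the 44 genes named by the rule, 15 moved by more than 1.5 times from the plain ratio under at least 1 setting, all 15 with a pseudocount of 5 RPKM; a value near 0 in a group makes the ratio depend on what is added to it. The quantile and median shift settings also carry a pseudocount of 1, with which alone 133 genes were at 2-fold or more. In all, 20 of the 135 genes were under 2-fold in at least 1 of the pseudocount, quantile and median shift settings, 15 of them with quantile normalization and the pseudocount of 1 together. There the log2 ratio was 0 for Bo4g182560, 0.53 for Bo8g036840, 0.68 for Bo3g052490, 0.83 for Bo6g072820 (ACA11), 0.87 for Bo3g009320, 0.97 for Bo8g106450 and -0.89 for Bo4g019850. The columns' medians differed by 0.036 on the log2(RPKM + 1) scale, and 129 genes were at 2-fold or more with the median shift and the pseudocount of 1 together. No paired analysis was possible because the table has 1 value per group and no library columns. For the same reason the fits without single libraries, with and without the limma trend, fry, and the planned adjusted p limit of 0.10 were not run. The plan left out camera for a table with only a part of the genes, since there is no background. The unknown read depth limits what can be said of genes with a value near 0, such as Bo3g162790 and Bo2g017650, both under 1 RPKM with calcium.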

Other observations

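The gene groups and the tests in this part were chosen after the values were seen. The 8 genes picked here for a role in salicylic acid synthesis or its response were all higher with calcium, from 2.25-fold to 26.6-fold. They were picked with their values known, so this count does not describe all genes of that pathway. The 8 had a median log2 ratio of 1.97, at percentile 95.9 of the matched random lists, inside the range of 95% of them (-2.04 to 2.05). Besides the GH3 gene, both ICS1 homologues, WRKY 70, PR1 and PR-2, they were a calmodulin-binding protein gene (Bo7g094930, 4.84-fold), whose Arabidopsis match is known to activate ICS1, and DMR6 (Bo2g159320, 2.25-fold), an enzyme that hydroxylates salicylic acid. All 6 genes annotated as trypsin or protease inhibitors were lower, from 2.09-fold to 30.6-fold, and their summed RPKM was 1184 with water and 417 with calcium. The cotyledon and leaf markers were lower in the same samples, by a median of 2.35-fold. With a median log2 ratio of -2.30, the inhibitors lay at percentile 0.18 of the matched random lists, on a list chosen for its direction. The most abundant of them, TI1 (Bo4g019850), was at 643 and 308 RPKM, and 1.85-fold lower under quantile normalization. The jasmonate-responsive VSP2 was also lower, whereas the defensin genes PDF1.1, 1.2C and 1.3 were higher.

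Of the genes annotated with heavy metals, cadmium or zinc, 6 were higher, and the metallothionein MT3, which those words leave out, was lower. With a median log2 ratio of 1.62, the 6 lay at percentile 75.4 of the matched random lists. They were both homologues of plant cadmium resistance 2, the zinc induced facilitator gene ZIF1 (Bo3g009320, 2.18-fold, and 1.83-fold under quantile normalization) and 3 genes of the heavy metal transport and detoxification superfamily, of which HIPP22 (Bo01260s010) was 5.58-fold higher. The 3 lipid transfer protein genes were higher, from 2.65-fold to 5.57-fold, with a summed RPKM of 340 with water and 1444 with calcium. Genes for DNA precursors and DNA repair, TSO2 (2 genes) and the BRCA1 homologue, were lower in 3 of 3 cases, beside the lower leaf markers (median 2.35-fold) in the same samples; no percentile was computed for so few genes.

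The leaf markers were lower with calcium in 12 of 12 listed cases. A smaller share of cotyledon or leaf tissue in the calcium samples may give this, and so may a lower level of the same transcripts within hypocotyl cells after the calcium spray. The count itself raised the first explanation and so does not test it, and the table, which holds only genes past a 2-fold limit, would hide leaf markers that kept their level. Both stay open.

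A shift of scale was weighed for the 71 higher genes: abundant leaf transcripts that took more of the water reads would lower all other values there by a common factor. The highest and the lowest difference among the higher genes were 13.3 times apart, where 1 factor would give like differences. Without a spread between libraries, and with the highest ratio resting on a value of 2.30 RPKM with water, this does not exclude a shift of scale as part of the picture. The 12 leaf markers summed to 15889 RPKM with water and 7147 RPKM with calcium. Their share of all reads could not be computed without gene lengths, so the size of such a shift is unknown. The calcium spray itself, other differences between the samples, and spread between libraries stay open, since no value per library was at hand.

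The order of the deposited adjusted p-values is consistent with a test of 2 proportions on the RPKM values, with no term for the spread between libraries: 0.0229% of the gene pairs were out of order at the ratio of totals fitted to them, 0.979. With equal totals 3.64% were, so the match rests on a ratio that was fitted and not known from the sources. Under this hypothesis the adjusted p describes the size and level of a difference between 2 values and carries no information on replicates. It would also keep genes of low RPKM out of the table. To reach the smallest z in the table, 3.68, a gene at exactly 2-fold would need 76.5 RPKM in calcium if higher, or 87.0 RPKM in water if lower. A gene at 0 in the other group would need 13.3 or 13.9 RPKM. The lowest value found in the higher of a gene's groups, 25.8 RPKM, lies above these last limits, and what set it was not tested.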
